A study of Etheostoma caeruleum with 79 samples.

How the data were processed

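The samples were livers of adult rainbow darter from 3 sites (US2, DSW and DSK1) in each of 4 years, with 6 or 7 arrays in each of the 12 groups and 79 in all. Each array has its own specimen number in the labels, apart from 2 numbers that are each on 2 arrays. Per the series text, 86 samples were processed and 7 arrays that failed quality control are not in the series, US2 fish were males, and the authors used a one-way ANOVA within each year with US2 as the control. Total RNA was labelled with one dye and hybridised to a custom array of 60-base probes. The arrays sat on 11 slides, with 5 to 8 of the arrays used here on each, and were scanned on 3 days (20, 31 and 28 arrays).

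The deposited scanner files hold fluorescence intensity per spot, which Agilent Feature Extraction 10.1.1.1 had corrected for background and for trends over the array, per the file headers. Raw spot and local background intensities are in the same deposited files. Per the file headers, the other columns used are flags of 0 or 1 for spots well above background, for outliers and for saturation. The authors' value table, as deposited, holds log2 values; how it was made is not given in the sources used here. Its columns have nearly the same distribution (medians from 7.61 to 7.65), as after quantile normalisation, and a floor of 4 that holds 15.1% of the values. It lacks the 18 custom probes. Its ranks followed those of the scanner signal (Spearman correlations from 0.9975 to 0.9984 per array).

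Of 15744 spots, 536 controls were left out, as were spots with an outlier flag (0 to 1998 per array, median 38). Spots of one probe were averaged, which gave 9041 probes, of which 2897, 6121 and 23 had 1, 2 and 3 spots. The log2 of the corrected signal less that of the 75th percentile of the array was analysed. A probe was tested if it was well above background on at least 0.5 of the arrays of at least 1 group, which left 7587 probes. After outlier spots were left out, 3835 values in 1238 of the probes were missing. The limit of precision is the signal over background, which was 40.3% to 91.2% of spots well above it, and the spread between 6 or 7 fish.

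Before the data were examined, the comparisons, the test, the filter, the rule for repeated specimen numbers and most alternatives were fixed. Each site was compared with each other site within a year by limma 3.58.1 in R 4.3.3 (linear model with empirical Bayes moderation and an intensity trend) on the arrays of that year. Differences between years used 1 model of all 12 groups. For each probe the model takes a spread shared by its groups, so SE and p are not exact where groups differ in spread. A probe passed at a Benjamini-Hochberg adjusted p under 0.05, over the probes of each comparison. For speed the model was computed directly and checked against limma (largest difference in p 1.4e-14). Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

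The method was tested on simulated data with 200 of 7587 probes changed. The noise was normal and drawn for each probe on its own, with the moderated spread of the model, equal in all groups. It held no batch effect, so the rates apply under the assumptions of the model and not to groups of unequal spread. In DSW against US2 it recovered between 44.8% and 65.7% of the 2-fold changes and between 87.9% and 90.9% of the 4-fold changes within a year. In DSK1 against US2 it recovered between 32.8% and 50.7% of the 2-fold changes, and for the difference of 2014 less 2011 it recovered 22.4% at DSW and 19.4% at DSK1. All recovered probes had the right sign. The most unchanged probes called were 11, of 120 calls for DSK1 against DSW in 2011 and of 123 in 2014. The fewest were 1, of 117 calls for DSW against US2 and of 91 for DSK1 against DSW in 2013.

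The alternatives were normexp background correction (offset 50) with quantile normalisation, quantile normalisation of the corrected signal, the authors' value table, no filter, and only the 3105 probes well above background on every array. Others were the slide as a fixed or random block (intraclass correlation 0.0608), all groups in 1 model, the arrays of a repeated specimen number averaged, each array left out in turn, and the one-way ANOVA with and without adjustment. In the ANOVA a probe was called when the test over the 3 sites passed, with or without adjustment, and the pairwise contrast had an unadjusted p under 0.05. As the contrast was never adjusted, the ANOVA counts with adjustment can also take in a difference at another site. The day of scanning and the slide row as blocks, removal of each array's trend on probe GC content (spline of 4 degrees of freedom), the removal of 4 arrays with under 50% of spots well above background, and 8 further differences between years were added after the data were seen. The overlap of the 2 lists that share the DSW arrays of 2013 was also computed with permuted labels and with those arrays divided, both added after the data were seen. Tests of lists in other years used all splits of the site labels, and correlations between years 10000 permutations, after fewer had been seen. Group labels were also permuted 100 times per comparison, the real grouping counted among them.

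The rule fixed beforehand for the probes to name called for gene names, which the files do not give in a form that could be read (the gene name column holds the probe ID, or a number or another code for the 18 custom probes). It was replaced by a rule that takes the 2 probes with the largest rise and the 2 with the largest fall among those past the threshold and well above background on at least 1 array of each group compared, or the 2 with the smallest p where none passed. This replacement was written after first fits had been looked at, so the named probes are not a choice made blind to their values. Any further probe named was picked after its values were seen. Fixed lists of genes and of cell-type markers (37 lists) could not be matched to the probes and were not used here. Probe sequences were not searched against other sequences.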

Results

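Liver RNA of adult rainbow darter (Etheostoma caeruleum), a small bottom-dwelling stream fish, was measured on 79 one-colour oligonucleotide arrays. The fish came from 3 sites on the Grand River in Ontario. US2 is the upstream site that served as the control, DSW lies below the wastewater plant of Waterloo, and DSK1 lies below the wastewater plant of Kitchener. Collections were made in 2011, 2012, 2013 and 2014, a period that, by the series title, covered upgrades of the plants. In these years in order, US2 had 6, 7, 7 and 6 arrays, DSW had 6, 7, 7 and 7, and DSK1 had 6, 7, 6 and 7. Each array held the RNA of a separate fish by the specimen numbers in the labels, apart from 2 numbers that each occur on 2 arrays (DSW 2013 replicates 1 and 6, and DSK1 2013 replicates 1 and 4). Within these pairs the correlations of values centred on the group mean were −0.135 and 0.377. By this measure, fixed beforehand, in neither pair was each array the closest to the other among all 79, and they were kept as separate samples. Values that were not centred correlated at 0.949 in the DSW pair, below the best other array of each (0.973 and 0.968), and at 0.983 in the DSK1 pair, above the best others (0.970 and 0.973), so the arrays of the DSK1 pair may come from the same fish. By specimen number DSW 2013 holds 6 fish on 7 arrays and DSK1 2013 holds 5 on 6, and arrays are counted in these groups, also where fish are written.

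Each array carried 9041 probes of 60 bases. Between 40.3% and 91.2% of the spots of an array (median 76.1%) were well above their background, and no spot was saturated. The 75th percentile of the signal ranged from 346 to 3397 fluorescence units (median 1007). Arrays in the upper row of a slide had 81.5% ± 3.9 (SD, 38 arrays) of spots well above background, and arrays in the lower row 64.5% ± 9.5 (SD, 41 arrays). Levels are given as log2 signal relative to the 75th percentile of the same array, and 7587 probes with enough signal were tested. The files describe no probe, and their gene name column repeats the probe ID except for the 18 custom probes, where it holds a number (16 probes) or another code and no gene name that could be read, so probes are named by their IDs. Where a probe was well above background on few arrays of a group, the fold against that group depends on the background and is not exact. Folds or log2 differences under normexp background correction with quantile normalisation, which adds an offset to the signal, are given beside those that it made smaller by over 1.5 times.

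The comparison of DSW with US2 within a year asked how the liver transcriptome below the Waterloo plant differed from that upstream. In 2011, 297 probes differed between the sites, 136 higher and 161 lower at DSW. The higher probes had a median log2 difference of 0.95 and the lower probes of −0.97, and 60 and 77 of them differed by over 2-fold. The largest fall was in probe GT_EA516_an_s_xh_2370 (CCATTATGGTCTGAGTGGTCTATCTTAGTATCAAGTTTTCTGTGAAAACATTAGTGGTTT), whose level was −3.83 ± 2.38 (SD, 6 fish) at DSW and 3.25 ± 1.36 (SD, 6 fish) at US2. It was 135-fold lower at DSW, a log2 difference of −7.08 ± 0.87 (SE; limma adjusted p = 0.000274), and all 6 DSW fish lay below every US2 fish. Probe GT_EA516_an_s_sp_3198, which shares no more than 5 bases in a row with it, was 79.7-fold lower (log2 difference −6.32 ± 0.77, SE; limma adjusted p = 0.000274), again in 6 of 6 fish. Without DSW replicate 5 the log2 differences were −8.01 and −7.10, and under normexp with quantile normalisation −5.57 and −4.37 (47.6-fold and 20.7-fold lower). These probes were well above background on 3 and 2 of the 6 DSW arrays and on all 6 US2 arrays. They also moved in the same direction in the comparisons below, and whether they are independent readings was not determined. Of the probes that rose, GT_EA516_an_as_sp_4945 and GT_EA516_an_as_sp_4946 had the largest changes, of 11.2-fold (log2 difference 3.49 ± 0.76, SE; limma adjusted p = 0.0149) and 11-fold (log2 difference 3.46 ± 0.66, SE; limma adjusted p = 0.00777). Both lay above every US2 fish in 5 of the 6 DSW fish, and the first was well above background on 3 of the 6 US2 arrays and had a log2 difference of 2.81 without DSW replicate 6. Whether this pair gives independent readings was not determined either.

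As the probes of a list were chosen on the same arrays, medians within batches agree in direction in part by construction, here and in the comparisons below. In 2011 the median log2 difference of the higher probes lay between 0.63 and 1.31 within the 3 days of scanning and between 0.53 and 1.44 within 4 slides, and that of the lower probes between −1.19 and −0.73 and between −1.23 and −0.69. The count was 72 by one-way ANOVA, in which only the test over the 3 sites was adjusted. It was 182 without US2 replicate 6, 181 without DSW replicate 2, 192 without DSW replicate 3 and 449 without DSW replicate 5. Among the probes well above background on every array, 220 passed, with 128 higher and 92 lower, so that the majority lay on the other side. Fitted with the slide as a fixed block, 341 passed, 184 higher and 157 lower, beside 348 in the same model of all 12 groups with no block. The call for GT_EA516_an_as_sp_4945 ended under normexp background correction with quantile normalisation (log2 difference 1.90, 3.72-fold, limma adjusted p = 0.0616, with a range from 0.000306 to 0.0616 over 12 settings).

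**Figure D1:**
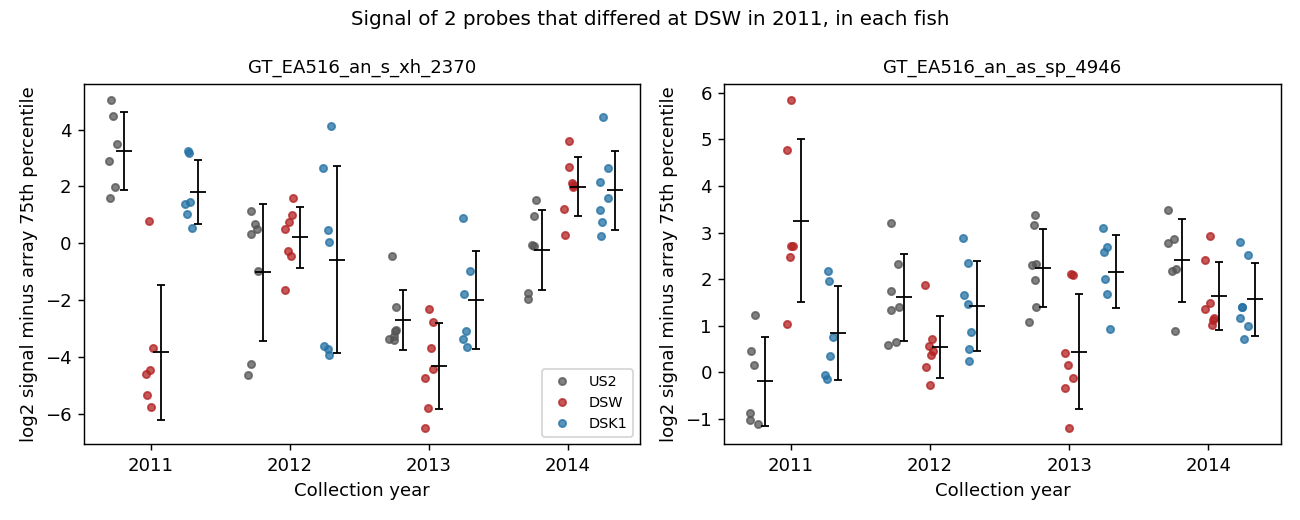
Normalised log2 signal (vertical axis, relative to the 75th percentile of the array) of a probe that fell and a probe that rose at DSW in 2011, by year (horizontal axis) and site. Each point is a fish and the bars are means with SD; in 2011 the fish of DSW averaged −3.83 and those of US2 3.25 for the first probe, and the DSK1 fish averaged 1.81.

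In 2012, limma called 0 probes between DSW and US2, with 593 probes at an unadjusted p under 0.05. One-way ANOVA called 1 probe after adjustment and 368 before it. The probes with the smallest p were GT_EA516_un_s_sp_20484, 2.93-fold higher at DSW (log2 difference 1.55 ± 0.28, SE; limma adjusted p = 0.0765) and above every US2 fish in 6 of 7 fish, and GT_EA516_an_s_xh_1714, 1.67-fold higher (log2 difference 0.74 ± 0.15, SE; limma adjusted p = 0.146). DSW replicate 4 stood against the rest of its group. Without it 12 probes passed, and the limma adjusted p of the probes just named became 0.000105 and 0.0113. Over 12 alternative settings the limma adjusted p of GT_EA516_un_s_sp_20484 ranged from 0.0145 to 0.222, and it missed the threshold in 5 of them. With the slide as a fixed block it passed (log2 difference 1.61, limma adjusted p = 0.0416). GT_EA516_an_s_xh_1714 missed the threshold in all 13 of its settings.

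The difference between DSW and US2 was widest in 2013, when 917 probes passed, 564 higher and 353 lower at DSW, or 642 with the 2 arrays of one specimen number averaged. Their median log2 differences were 0.96 and −0.92, and 270 and 149 of them differed by over 2-fold. The 2 largest rises were in probes of a class of 18 custom sequences on the array. CUST_4_PI428058183 (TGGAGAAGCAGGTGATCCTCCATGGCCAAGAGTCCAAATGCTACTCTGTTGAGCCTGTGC) stood at 2.79 ± 4.63 (SD, 7 arrays of 6 specimen numbers) at DSW and −4.83 ± 0.64 (SD, 7 fish) at US2, 196-fold higher at DSW (log2 difference 7.61 ± 1.46, SE; limma adjusted p = 0.00303). CUST_3_PI428058183 (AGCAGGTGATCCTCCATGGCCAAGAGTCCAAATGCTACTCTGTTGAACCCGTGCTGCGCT) was 184-fold higher (log2 difference 7.52 ± 1.51, SE; limma adjusted p = 0.00377). The sequences of this pair share a run of 46 bases, so they are not independent readings. For each, 6 of the 7 DSW arrays lay above every US2 fish, and 4 and 5 of the 7 US2 arrays were well above background. The folds moved by over 1.5 times with single arrays: without DSW replicates 3, 4, 5 and 7 in turn, the log2 difference was 8.33, 6.84, 6.77 and 8.92 for CUST_4_PI428058183 and 8.24, 6.75, 6.68 and 8.88 for CUST_3_PI428058183. Under normexp background correction with quantile normalisation it was 6.04 and 6.30 (65.6-fold and 78.9-fold). Of the 13 custom probes tested, 4 were higher and 1 was lower at DSW, and 6 were higher and 2 lower when adjusted over the class alone. The largest falls were in GT_EA516_un_as_xh_1201, 6.02-fold lower at DSW (log2 difference −2.59 ± 0.53, SE; limma adjusted p = 0.00421), and GT_EA516_an_s_sp_1007, 5.70-fold lower (log2 difference −2.51 ± 0.72, SE; limma adjusted p = 0.0270), below every US2 fish in 6 and 5 of the 7 arrays. They were 3.17-fold and 2.61-fold lower under normexp with quantile normalisation, and the second was 9.39-fold lower with the slide as a fixed block.

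**Figure D2:**
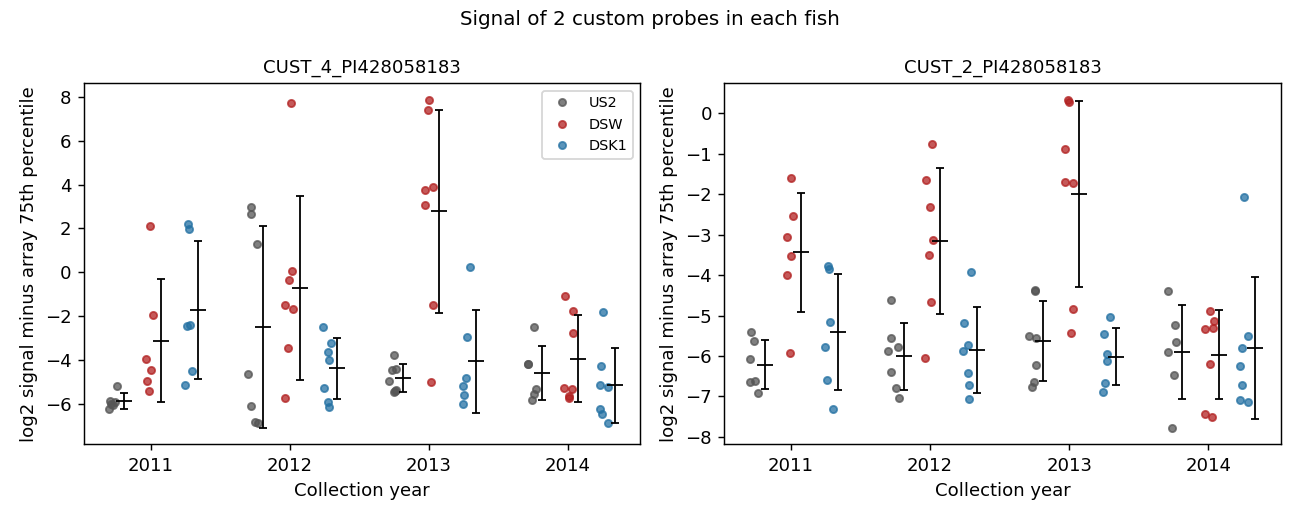
Normalised log2 signal (vertical axis, relative to the 75th percentile of the array) of CUST_4_PI428058183 (left) and CUST_2_PI428058183 (right) by year (horizontal axis) and site, with a point for each fish and bars for mean and SD. For CUST_4_PI428058183, 6 of the 7 DSW arrays of 2013 lie above every US2 fish of that year, with group means of 2.79 and −4.83.

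Fish of DSW in 2013 were not alike. As deviations from the mean of all 79 arrays, the 564 higher probes averaged 0.80 ± 0.50 (SD, 7 arrays) at DSW and −0.27 ± 0.11 (SD, 7 fish) at US2, but 0.04 and 0.16 in DSW replicates 3 and 7. Without these fish, one at a time, 1440 and 1444 probes passed. As the SE and p of limma rest on a spread shared by the sites, they are not exact here, where DSW varied more than US2. The count was 602 without US2 replicate 4, 563 without DSW replicate 4 and 543 without DSW replicate 5. With the 2 arrays of one specimen number averaged it was 642, and GT_EA516_an_s_sp_1007 no longer passed (log2 difference −2.26, limma adjusted p = 0.0612, with a range from 0.000849 to 0.0612 over 12 settings). That probe also missed the threshold without US2 replicate 7 or without DSW replicate 1, 4, 5 or 6 (limma adjusted p up to 0.0647). Of the probes well above background on every array 521 passed, with 225 higher and 296 lower. Fitted with the slide as a fixed block, 1245 passed, 722 higher and 523 lower, and the model of all 12 groups with no block also gave 1245, 701 higher and 544 lower. The median log2 difference of the higher probes was between 0.88 and 1.2 within the 3 days of scanning and 1.17 and 1.27 within the 2 slides that held both sites, and that of the lower probes was between −1 and −0.85 and between −1.07 and −0.90.

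**Figure D3:**
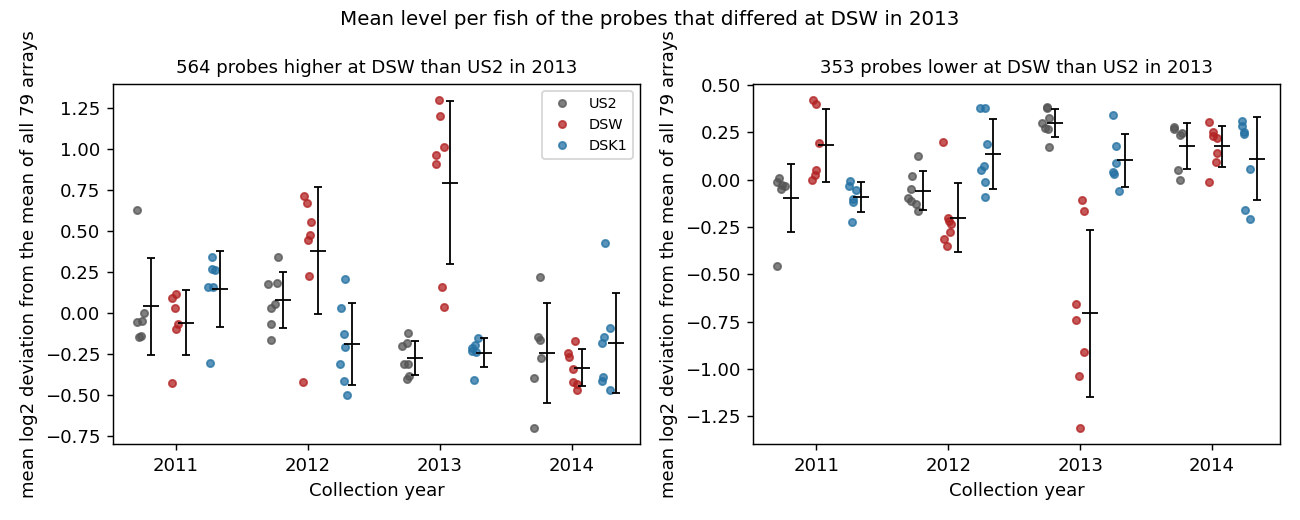
Mean log2 deviation from the mean of all 79 arrays (vertical axis) of the probes that were higher (left, 564 probes) or lower (right, 353 probes) at DSW than at US2 in 2013, for each fish by year (horizontal axis) and site, with bars for mean and SD. The probes were chosen on the 2013 fish, which stand apart by construction; DSW fish averaged 0.38 in 2012 and −0.33 in 2014 for the higher probes.

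In 2014 DSW and US2 differed in 1 probe, GT_EA516_an_s_sp_3695, which was 2.43-fold lower at DSW (log2 difference −1.28 ± 0.21, SE; limma adjusted p = 0.0364), in 7 of 7 fish below every US2 fish. By limma 440 probes had an unadjusted p under 0.05, and one-way ANOVA called 2 probes after adjustment and 244 before it. With the slide as a fixed block 0 probes passed by limma (log2 difference of the named probe −1.23, adjusted p = 0.487, with a range from 0.0204 to 0.487 over 13 settings). The model of all 12 groups with no block also gave 0, so this loss cannot be put down to the slide. The call also ended when any one of US2 replicates 1, 2, 3 and 5 or any one of the DSW fish was left out (limma adjusted p up to 0.157), and 2 probes passed without US2 replicate 4.

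**Figure D4:**
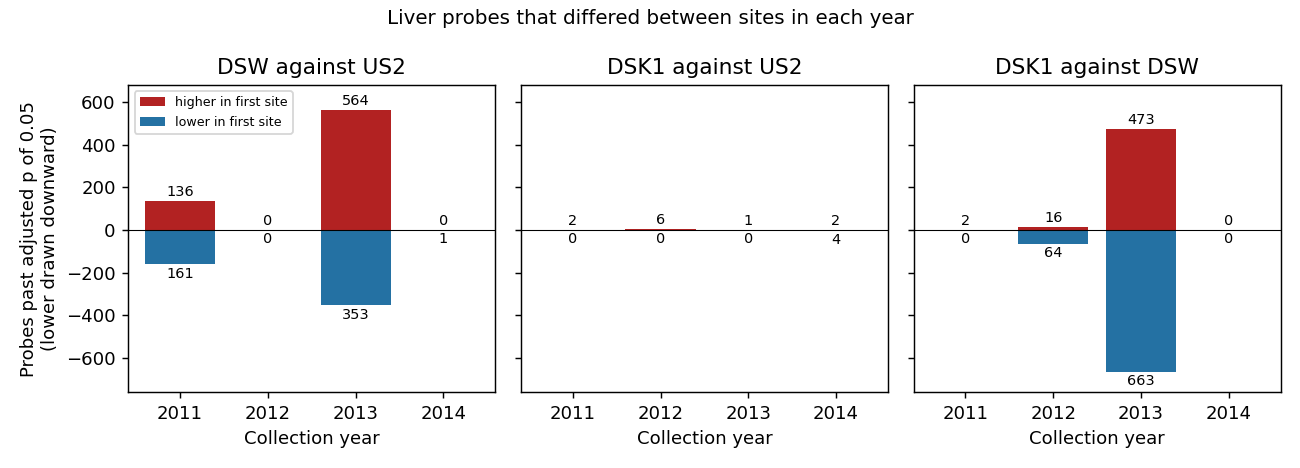
Number of probes with a limma adjusted p under 0.05 that were higher (up) or lower (down) in each comparison of sites, by year. DSW differed from US2 in 297 probes in 2011 and 917 in 2013, and DSK1 differed from US2 in 6 probes or fewer in every year.

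Below the Kitchener plant, differences from US2 were few in each year. In 2011, 2 probes passed, both higher at DSK1 in 6 of 6 fish than in any US2 fish. GT_EA516_un_s_xh_10404, which was also 4-fold higher at DSW that year against the same US2 fish, was 3.05-fold higher at DSK1 (log2 difference 1.61 ± 0.24, SE; limma adjusted p = 0.0134) and GT_EA516_un_s_sp_47170 was 2.71-fold higher (log2 difference 1.44 ± 0.23, SE; limma adjusted p = 0.0134). With the slide, the day of scanning or the row on the slide as a block 0 probes passed (with the slide as a fixed block limma adjusted p = 0.0833 and 0.169, with ranges from 0.0058 to 0.132 and from 0.00679 to 0.183 over 12 settings). The model of all 12 groups with no block also gave 0, so the loss cannot be put down to the blocks. One-way ANOVA, whose adjusted test also takes in the difference at DSW, called 42. By limma 548 had an unadjusted p under 0.05. The count was 1 without DSK1 replicate 1 or 2, which ended the call for GT_EA516_un_s_sp_47170 (limma adjusted p up to 0.0538), 8 without US2 replicate 6, and 9 without US2 replicate 5 or DSK1 replicate 5.

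In 2012, 6 probes were higher at DSK1 than at US2 and 0 were lower. The largest rises were in GT_EA516_an_s_sp_1077, 11.9-fold (log2 difference 3.57 ± 0.64, SE; limma adjusted p = 0.0244), and GT_EA516_an_as_sp_2221, 4.68-fold (log2 difference 2.23 ± 0.44, SE; limma adjusted p = 0.0499), each with 6 of 7 fish above every US2 fish. They were well above background on 5 of the 7 DSK1 arrays and on 1 and 2 of the 7 US2 arrays. The rises were 2.35-fold and 1.51-fold under normexp with quantile normalisation (limma adjusted p = 0.0780 and 0.473) and 5.06-fold and 3.11-fold in the authors' value table (0.287 for both), and the first was 7.45-fold with quantile normalisation alone (0.227). By limma, 730 probes had an unadjusted p under 0.05. With the slide as a fixed block 0 probes passed (limma adjusted p = 0.132 for both, with ranges from 0.0232 to 0.287 and from 0.0451 to 0.473 over 12 settings), and 2 passed with quantile normalisation. One-way ANOVA called 3 after adjustment and 422 before it. Left out one at a time, US2 replicate 1 and DSK1 replicate 1 gave 0 probes, US2 replicates 2, 4 and 5 and DSK1 replicates 6 and 7 gave 2, US2 replicate 7 and DSK1 replicate 3 gave 3, and the highest count was 9. The first of the named probes no longer passed without any one of these 9 arrays (limma adjusted p up to 0.0900). The second failed without any array but US2 replicate 3 and DSK1 replicate 3 (limma adjusted p up to 0.179).

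In 2013 DSK1 differed from US2 in 1 probe, GT_EA516_un_s_sp_11267, 1.97-fold higher at DSK1 (log2 difference 0.98 ± 0.16, SE; limma adjusted p = 0.0233) and above every US2 fish in 6 of 6 fish. Unadjusted p was under 0.05 for 616 probes. The call ended with the slide as a fixed block (limma adjusted p = 0.201, with a range from 0.00779 to 0.244 over 13 settings) and with the 2 arrays of one specimen number averaged (0.0733). The model of all 12 groups with no block also gave 0 probes, so the former loss cannot be put down to the slide. Without US2 replicate 1, 3, 4, 5 or 6 or DSK1 replicate 2, 4 or 5 the call ended as well (limma adjusted p up to 0.122), while 8 probes passed without US2 replicate 2 and 3 without DSK1 replicate 3. One-way ANOVA, whose test over all 3 sites also takes in the difference at DSW, called 151 probes after adjustment and 459 before it.

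In 2014, 6 probes differed between DSK1 and US2, 2 higher and 4 lower. GT_EA516_an_s_sp_3695, the probe that fell at DSW in the same year, was 3.10-fold lower at DSK1 (log2 difference −1.63 ± 0.21, SE; limma adjusted p = 0.000940), in 7 of 7 fish below every US2 fish. As both sites were set against the same US2 fish, the falls are not independent. GT_EA516_un_as_xh_1937 was 2.33-fold lower (log2 difference −1.22 ± 0.24, SE; limma adjusted p = 0.0487), in 5 of 7 fish below every US2 fish. The rises were in GT_EA516_an_s_sp_2983, 7.46-fold (log2 difference 2.90 ± 0.47, SE; limma adjusted p = 0.00937), and GT_EA516_an_s_sp_2034, 3.62-fold (log2 difference 1.86 ± 0.29, SE; limma adjusted p = 0.00680), each in 7 of 7 fish; the first was well above background on 3 of the 6 US2 arrays and was 3.42-fold higher under normexp with quantile normalisation. With the slide as a fixed block 0 probes passed (limma adjusted p = 0.173, 0.530, 0.516 and 0.516 in the order named, against lowest values of 0.000518, 0.0327, 0.00497 and 0.00133 over all settings). With quantile normalisation 5 passed, 1 higher and 4 lower. One-way ANOVA called 4 after adjustment and 344 before it, and 560 had an unadjusted p under 0.05 by limma. The count was 3 without US2 replicate 1 or 3, 21 without US2 replicate 4 and 14 without DSK1 replicate 4. GT_EA516_un_as_xh_1937 missed the threshold without US2 replicate 1, 2, 3, 5 or 6 or DSK1 replicate 1, 2, 3 or 7 (limma adjusted p up to 0.174). It also missed it in 10 of 13 alternative settings. GT_EA516_an_s_sp_3695 did so in 1 of 13, GT_EA516_an_s_sp_2983 in 6 of 12 and GT_EA516_an_s_sp_2034 in 4 of 12.

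The exposed sites were also set against each other within each year. In 2011 only GT_EA516_an_s_xh_2370 and GT_EA516_an_s_sp_3198 differed, 49.9-fold (log2 difference 5.64 ± 0.87, SE; limma adjusted p = 0.0182) and 28.4-fold (log2 difference 4.83 ± 0.77, SE; limma adjusted p = 0.0182) higher at DSK1 than at DSW, each in 5 of 6 fish above every DSW fish. Without DSW replicate 5 the log2 differences were 6.57 and 5.61, and under normexp with quantile normalisation 4.10 and 3.06 (17.2-fold and 8.35-fold). Both calls ended without any one of DSW replicates 1, 2, 3, 4 and 6 or DSK1 replicates 2, 3 and 6 (limma adjusted p up to 0.0769), and 36 probes passed without DSW replicate 5. With quantile normalisation 15 passed, 10 higher and 5 lower, and one-way ANOVA, whose adjusted test covers all sites of the year, called 61. Without the 4 arrays that had under 50% of spots well above background, 0 passed (limma adjusted p = 0.0621 for both, with a range from 0.000917 to 0.0621 over 12 settings). GT_EA516_an_s_sp_3198 also missed the threshold under normexp background correction with quantile normalisation (0.0501). One-way ANOVA called 685 before adjustment, and 1005 had an unadjusted p under 0.05 by limma.

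In 2012, 80 probes differed between DSK1 and DSW, 16 higher and 64 lower at DSK1, with median log2 differences of 1.33 and −1.15. GT_EA516_un_s_sp_43129 was 9.23-fold lower at DSK1 (log2 difference −3.21 ± 0.66, SE; limma adjusted p = 0.0276), and the custom probe CUST_2_PI428058183 was 6.48-fold lower (log2 difference −2.70 ± 0.64, SE; limma adjusted p = 0.0414). They were well above background on 6 of the 7 DSW arrays and on 1 of the 7 DSK1 arrays, and 1 and 3 of the 7 DSK1 fish lay below every DSW fish. The log2 difference of the first was −3.83 without DSW replicate 4, and under normexp with quantile normalisation the falls were 3.15-fold and 2.33-fold. Higher at DSK1 were GT_EA516_un_as_sp_12466, 10.4-fold (log2 difference 3.38 ± 0.66, SE; limma adjusted p = 0.0276), and GT_EA516_an_s_sp_4674, 4.02-fold (log2 difference 2.01 ± 0.46, SE; limma adjusted p = 0.0414), well above background on 1 and 7 of the 7 DSW arrays and above every DSW fish in 7 and 4 of 7 fish; the first was 2.95-fold higher under normexp with quantile normalisation. The median of the lower probes was between −1.69 and −0.75 within days of scanning, and that of the higher probes between 0.93 and 1.44. This count was among the least stable. It was 140 with the slide as a fixed block, beside 224 in the same model of all 12 groups with no block. One-way ANOVA called 4, and 17 (8 higher, 9 lower) passed without the arrays under 50% well above background. Left out one at a time, DSW replicates 3, 5, 6 and 7 gave 0 probes, DSW replicate 2 and DSK1 replicate 1 gave 1, and DSK1 replicates 3, 7 and 2 gave 17, 31 and 45. DSW replicate 1 gave 37 and DSW replicate 4 gave 233. Each of the 4 named calls ended without any one of DSW replicates 2, 3, 5, 6 and 7 or DSK1 replicates 1 and 3. Those of GT_EA516_an_s_sp_4674 and CUST_2_PI428058183 also ended without DSK1 replicate 4 or 7, that of the former without DSK1 replicate 2, and that of the latter without DSK1 replicate 6 (limma adjusted p up to 0.104 for the 4 probes). GT_EA516_un_s_sp_43129 missed the threshold in the authors' value table (limma adjusted p = 0.219, with a range from 0.00404), and CUST_2_PI428058183 under normexp with quantile normalisation and without the arrays under 50% (limma adjusted p = 0.0547 and 0.0831, with a range from 0.00919). GT_EA516_an_s_sp_4674 was past the threshold with the slide neither as a fixed nor as a random block (limma adjusted p = 0.0954 and 0.0680, with a range from 0.0297 to 0.109 over 13 settings).

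In 2013, 1136 probes differed between DSK1 and DSW, 473 higher and 663 lower at DSK1. The custom pair again had the largest falls, with CUST_3_PI428058183 121-fold lower (log2 difference −6.92 ± 1.58, SE; limma adjusted p = 0.00651) and CUST_4_PI428058183 114-fold lower at DSK1 (log2 difference −6.84 ± 1.52, SE; limma adjusted p = 0.00560). Of the 6 DSK1 arrays 2 and 3 lay below every DSW array, and all 6 below the DSW mean. Without DSW replicates 3, 4, 5 and 7 or DSK1 replicate 2 in turn, the log2 difference was −7.63, −6.14, −6.08, −8.27 and −7.81 for the first and −7.55, −6.07, −5.99, −8.14 and −7.70 for the second. Under normexp with quantile normalisation they were 53.9-fold and 47-fold lower. GT_EA516_un_s_sp_39737 was 27-fold higher (log2 difference 4.75 ± 1.15, SE; limma adjusted p = 0.00915) and GT_EA516_an_as_sp_1401 10.2-fold higher (log2 difference 3.35 ± 0.81, SE; limma adjusted p = 0.00915), each above every DSW array in 5 of 6 arrays. They were well above background on 3 and 2 of the 7 DSW arrays, and the custom pair on 4 of the 6 DSK1 arrays. The SDs of GT_EA516_un_s_sp_39737 and GT_EA516_an_as_sp_1401 were 4.13 and 2.46 at DSK1 but 0.50 and 0.76 at DSW. Their SE and p, which rest on a shared spread, are therefore not exact. For GT_EA516_un_s_sp_39737 the log2 difference within the 3 days of scanning was 9.09, 1.77 and 5.25. It was 3.97, 5.43, 3.99, 5.73 and 4.07 without DSK1 replicates 1, 3, 4, 5 and 6 in turn, 2.89 (7.42-fold) under normexp with quantile normalisation, 3.76 with the slide as a fixed block and 3.97 (15.6-fold) with the arrays of one specimen number averaged. For GT_EA516_an_as_sp_1401 it was 4.01 without DSK1 replicate 2 and 1.58 (2.99-fold) under normexp with quantile normalisation. Of the probes higher at DSW than at US2 in 2013, 434 were also higher at DSW than at DSK1, where 49.3 are expected of independent lists, and of those lower, 175 were lower against 22 expected. Both comparisons share the DSW arrays, so the expectation for independent lists is not that of no effect. With the labels of the 3 sites permuted 99 times, the overlap was 0 in each direction every time, a value that leaves out the effects. With the DSW arrays divided between the comparisons in 30 ways, those of one specimen number kept together, the mean overlap was 59 probes (range 0 to 166) for the higher, where 5.88 are expected of independent lists, and 12.1 (range 0 to 38) for the lower, where 2.08 are expected. With the 2 pairs of arrays of one specimen number averaged, 634 passed, and without DSW replicate 4, 735 passed. Of the probes well above background on every array 697 passed, with 427 higher and 270 lower. The medians within days of scanning were between 0.84 and 0.996 for the higher and between −1.23 and −0.93 for the lower probes.

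In 2014 limma called 0 probes between DSK1 and DSW, with 446 probes at an unadjusted p under 0.05. One-way ANOVA called 2 after adjustment and 251 before it. The smallest p values belonged to GT_EA516_an_as_sp_4573, at a log2 difference of −0.70 ± 0.14 (SE; limma adjusted p = 0.260), and GT_EA516_an_s_sp_1724, at −0.98 ± 0.21 (SE; limma adjusted p = 0.260).

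Whether the difference from US2 changed over the period of the upgrades was tested directly, as the difference of 2014 less that of 2011. At DSW 30 probes passed, 14 with a higher and 16 with a lower difference in 2014. GT_EA516_an_s_xh_2370 moved by 9.30 ± 1.39 (log2, SE; limma adjusted p = 1.45e-05) and GT_EA516_an_s_sp_3198 by 8.66 ± 1.21 (log2, SE; limma adjusted p = 4.07e-06), or by 10.2 and 9.45 without DSW 2011 replicate 5 and by 7.56 and 6.05 under normexp with quantile normalisation. In 2014 the first of them stood at 1.99 ± 1.04 (SD, 7 fish) at DSW and −0.23 ± 1.40 (SD, 6 fish) at US2, a log2 difference of 2.22 (limma adjusted p = 0.521). GT_EA516_an_as_sp_4945 moved by −4.24 ± 0.91 (log2, SE; limma adjusted p = 0.0105) and GT_EA516_an_as_sp_4946 by −4.22 ± 0.77 (log2, SE; limma adjusted p = 0.00115), the former by −3.56 without DSW 2011 replicate 6 and by −2.32 under normexp with quantile normalisation. At US2 itself these probes were higher in 2014 than in 2011, by 2.80 and 2.60, which is most of each move, and 8 of the 16 probes with a lower difference were called for a rise at US2 between these years. Of the probes higher at DSW in 2011, 15 were among those whose difference dropped, and of those lower, 12 were among those whose difference increased, an overlap that shares the 2011 fish. With quantile normalisation 36 passed, 21 higher and 15 lower. Without the arrays under 50% well above background 18 passed, and without DSW 2011 replicate 5, 50 passed. GT_EA516_an_as_sp_4945 missed the threshold with the slide as a fixed block (log2 −3.93, limma adjusted p = 0.0658, with a range from 0.00811 to 0.0658 over 11 settings).

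At DSK1 the difference from US2 was lower in 2014 than in 2011 for 6 probes and higher for 0. GT_EA516_un_s_xh_7876 moved by −2.48 ± 0.54 (log2, SE; limma adjusted p = 0.0327; −1.58 under normexp with quantile normalisation) and GT_EA516_un_s_xh_10404 by −2.37 ± 0.51 (log2, SE; limma adjusted p = 0.0327). The latter was also higher at US2 in 2014 than in 2011 (log2 difference 1.58, limma adjusted p = 0.0434, with a range from 0.0228 to 0.319 over 11 settings), a call that ended with the slide as a fixed block (0.140) and without any one of US2 2011 replicates 1, 2, 3 and 5 or US2 2014 replicates 1 to 5 (up to 0.186). With the slide as a fixed block 1 probe passed (limma adjusted p = 0.110 and 0.0585 for the named probes, with ranges from 0.0224 to 0.117 and from 0.0139 to 0.616 over 11 settings), and without the arrays under 50% well above background 0 passed, against 452 at an unadjusted p under 0.05 with all arrays. Left out one at a time, US2 2011 replicate 3, DSK1 2011 replicate 1 and US2 2014 replicate 4 gave 0 probes. US2 2011 replicates 1, 2 and 5, DSK1 2011 replicates 2 and 6, US2 2014 replicate 2 and DSK1 2014 replicates 6 and 7 gave 1, DSK1 2011 replicate 4 gave 2 and DSK1 2014 replicate 2 gave 3. DSK1 2014 replicate 4 gave 10 and US2 2011 replicate 6 gave 11. GT_EA516_un_s_xh_7876 lost its call without any one of the arrays that gave 3 probes or fewer and without US2 2011 replicate 4, and GT_EA516_un_s_xh_10404 without any one of the former except DSK1 2014 replicate 2 (limma adjusted p up to 0.109).

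The remaining differences between years were added after the data were seen. At DSW the difference from US2 changed in 489 probes from 2013 to 2014, with 346 of them lower and 143 higher in 2014. CUST_4_PI428058183 moved by −6.96 ± 2.12 (log2, SE; limma adjusted p = 0.0355, with a range from 0.0246 to 0.0562 over 10 settings). That call ended with the slide as a fixed block (0.0507), with the arrays of one specimen number averaged (0.0562) and without any one of DSW 2013 replicates 1, 2, 4, 5 and 6, US2 2014 replicate 4 or DSW 2014 replicates 3, 5 and 6 (limma adjusted p up to 0.0876). Without DSW 2013 replicates 3, 4, 5 and 7 in turn the move was −7.67, −6.19, −6.11 and −8.26, and under normexp with quantile normalisation −5.47. GT_EA516_un_s_sp_43129 moved by −5.58 ± 1.02 (log2, SE; limma adjusted p = 0.00272), or by −6.35 without DSW 2013 replicate 7; its log2 difference from US2 had been 3.37 in 2011 (limma adjusted p = 0.00206), 3.33 in 2012 (limma adjusted p = 0.202, and 3.96 with 0.000868 without DSW replicate 4) and 5.32 in 2013 (limma adjusted p = 0.00168, and 6.09 without DSW replicate 7), and was −0.26 in 2014 (limma adjusted p = 0.976). Under normexp with quantile normalisation the move was −3.20, and the differences were 1.43 in 2011, 1.62 in 2012 and 3.16 in 2013; in the authors' value table that of 2012 was 1.86. The probe was well above background on 1 of the 7 US2 arrays of 2013 and 1 of the 7 DSW arrays of 2014. These probes were picked after their values had been seen. The count for 2014 against 2013 was 283 with the arrays of one specimen number averaged and 318 among probes well above background on every array. Left out one at a time, US2 2013 replicates 2 and 4 gave 320 and 305, DSW 2013 replicates 1, 4 and 5 gave 274, 266 and 258, US2 2014 replicates 3 and 4 gave 320 and 190, DSW 2014 replicates 4 and 7 gave 322 and 307, and DSW 2013 replicates 3 and 7 gave 838 and 827. From 2011 to 2013 the difference changed in 1269 probes (749 higher, 520 lower), and in 714 (298 higher, 416 lower) of those well above background on every array. At DSK1 limma called 0 probes for 2012 against 2011, 0 for 2013 against 2011 and 0 for 2013 against 2012, with 606, 470 and 771 probes at an unadjusted p under 0.05, and 2 probes for 2014 against 2013, of which GT_EA516_an_s_sp_3695 moved by −2.25 ± 0.38 (log2, SE; limma adjusted p = 0.000962, and 0.0889 with the slide as a fixed block, with a range from 0.000441 over 12 settings). No ANOVA was run on these differences.

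The upstream site itself varied between years. Against 2011, 328 probes differed at US2 in 2013, 86 higher and 242 lower. GT_EA516_an_s_xh_2370 was 61.2-fold lower in 2013 (log2 difference −5.94 ± 0.96, SE; limma adjusted p = 9.22e-05) and GT_EA516_an_s_sp_3198 50-fold lower (log2 difference −5.64 ± 0.84, SE; limma adjusted p = 1.31e-05), each in 7 of 7 fish below every fish of 2011, or 35.3-fold and 17.4-fold lower under normexp with quantile normalisation. GT_EA516_an_s_sp_2358 was 25.3-fold higher (log2 difference 4.66 ± 1.14, SE; limma adjusted p = 0.00906) and GT_EA516_an_s_xh_378 was 17.3-fold higher (log2 difference 4.12 ± 1.20, SE; limma adjusted p = 0.0345), well above background on 2 and 5 of the 6 US2 arrays of 2011. Of the 7 fish of 2013, 3 and 5 lay above every fish of 2011. For GT_EA516_an_s_sp_2358 the log2 difference within the 3 days of scanning was 9.02, 5.29 and 0.27, so the rise was not seen on each day. It was 5.53, 3.69 and 5.28 without US2 2011 replicate 6, US2 2013 replicate 1 and US2 2013 replicate 7, 5.62 (49.2-fold) with the slide as a fixed block and 2.75 (6.71-fold) under normexp with quantile normalisation. The call for GT_EA516_an_s_xh_378, whose log2 difference was 3.41 without US2 2011 replicate 5 and 3.34 under normexp with quantile normalisation, ended without any one of US2 2011 replicates 2, 3, 4 and 5 or US2 2013 replicates 1, 3, 4 and 6 (limma adjusted p up to 0.101). Of the probes well above background on every array 176 passed, 66 higher and 110 lower, and with the slide as a fixed block 296 passed, 113 higher and 183 lower. Left out one at a time, US2 2011 replicates 2, 4 and 6 gave 188, 158 and 203 probes, and US2 2013 replicates 4, 6 and 7 gave 180, 186 and 214. The medians within days of scanning were between 0.98 and 0.999 for the higher probes and between −1.07 and −0.81 for the lower.

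For 2012 against 2011, 1 probe differed at US2, GT_EA516_an_s_sp_3198, 17.6-fold lower in 2012 (log2 difference −4.14 ± 0.84, SE; limma adjusted p = 0.0377), or 9.57-fold under normexp with quantile normalisation. It missed the threshold with the slide as a fixed block (limma adjusted p = 0.115, with a range from 0.00368 to 0.115 over 11 settings) and without US2 2011 replicate 1, 2, 3 or 6 or US2 2012 replicate 2 or 3 (up to 0.226 by limma). In these 6 cases 0 probes passed by limma, against 456 at an unadjusted p under 0.05 with all arrays; 2 passed without US2 2011 replicate 4 or US2 2012 replicate 4 or 6, and 6 without US2 2011 replicate 5. With quantile normalisation 4 passed, 2 higher and 2 lower. For 2014 against 2011, 9 probes differed, 8 higher and 1 lower. GT_EA516_an_as_sp_4945 and GT_EA516_an_as_sp_4946 were 6.96-fold (log2 difference 2.80 ± 0.65, SE; limma adjusted p = 0.0480) and 6.05-fold (log2 difference 2.60 ± 0.55, SE; limma adjusted p = 0.0329) higher in 2014, and GT_EA516_an_as_sp_1014 was 8.17-fold lower (log2 difference −3.03 ± 0.59, SE; limma adjusted p = 0.0158), with 5, 5 and 6 of the 6 fish beyond every fish of 2011. The first and last were 2.40-fold higher and 4.48-fold lower under normexp with quantile normalisation. With quantile normalisation 15 passed, 9 higher and 6 lower. Without the arrays under 50% well above background 0 passed by limma, and 778 had an unadjusted p under 0.05 with all arrays. Fitted with the slide as a fixed block 2 passed, and both named rises missed the threshold (limma adjusted p = 0.251 and 0.140, with ranges from 0.0408 to 0.251 and from 0.0188 to 0.160). Without US2 2011 replicate 1 or 3 or US2 2014 replicate 1 or 2, 0 passed. Without US2 2011 replicate 5 or US2 2014 replicate 3, 1 passed, without US2 2014 replicate 5, 4 passed, and without US2 2011 replicate 2 or 6, 5 passed. GT_EA516_an_as_sp_4946 lost its call in the cases with 0 or 1, and GT_EA516_an_as_sp_1014 in those with 0. GT_EA516_an_as_sp_4945 lost it in every case named and without US2 2014 replicate 6 (limma adjusted p up to 0.234 for the 3 probes).

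The 2011 and 2013 differences at DSW were not repeats of each other. Of the 136 probes higher at DSW in 2011, 10 were higher in 2013, where about 10 are expected of independent lists, and 40 were lower, where 6.33 are expected. Of the 161 lower, 2 were lower in 2013 and 2 higher, where 7.49 and 12 are expected. The probes called in 2011 had a mean log2 difference in their own 2011 direction of −0.21 in 2013 (permutation p = 0.0338, adjusted p = 0.101 by Benjamini-Hochberg over 12 such tests, all splits of the site labels, two-sided) and of 0.17 in 2012 (permutation p = 0.0227, adjusted 0.101). Those called in 2013 had a mean of 0.24 in 2012 (permutation p = 0.0816, adjusted 0.196), with 728 of 917 in the same direction, of −0.17 in 2011 (permutation p = 0.255, adjusted 0.51) and of −0.06 in 2014 (permutation p = 0.569, adjusted 0.636). At DSK1 in 2012 the probes called at DSW in 2013 had a mean of −0.24 (permutation p = 0.0274, adjusted 0.101), with 204 of 917 in the same direction. Of the 12 tests 1 passed after adjustment. Of the 64 probes lower at DSK1 than at DSW in 2012, 53 were higher at DSW than at US2 in 2013, against 4.76 expected of independent lists, with no array in common. The 80 probes of 2012 had a mean signed log2 difference of −1.02 in that comparison, which is the test that passed (permutation p = 0.00233, adjusted 0.028, with the 2 DSW arrays of one specimen number counted separately). In the first run, with 100 permutations, this test had a permutation p of 0.02 (adjusted 0.14), and none of the 12 passed.

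Across all 7587 probes, which are not independent replicates, the differences of DSW and DSK1 from US2 in the same year correlated at r = 0.512 in 2011, 0.482 in 2012, 0.316 in 2013 and 0.590 in 2014. Comparisons that share control fish correlate without any effect. With the site labels of the same arrays permuted within each year, the mean r was 0.496, 0.480, 0.442 and 0.525. The permuted arrays still hold any real site differences, so these values are not purely those of no effect. The covariances were 0.110, 0.0833, 0.0865 and 0.0789, against permuted means of 0.0676, 0.0631, 0.0587 and 0.0620 and highest permuted values of 0.133, 0.155, 0.185 and 0.137. With the US2 fish divided so that each site had its own controls, the mean r was 0.175, 0.132, 0.130 and 0.0670. Between years, none of the 12 correlations of a site's differences passed adjustment (10000 permutations). The lowest adjusted permutation p was 0.258, for DSW in 2012 and 2013 (r = 0.279, rho = 0.281, permutation p = 0.043) and for DSK1 in 2013 and 2014 (r = −0.238, rho = −0.185, permutation p = 0.033).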

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

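The covariation of probes between fish and the test for a shift of US2 in 2011 were written after their results had been seen in part, and the 8 further differences between years, the slide row and the GC trend were added after the data were seen, when principal components against the slide and the correlation of site differences with probe GC content had been looked at.

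Of 106 sets of group values tested, 6 held a fish far from the others. Chance gives about 1 in 20, so this is about as many as chance alone would give. The 75th percentile of the signal was 1221 in DSW 2011 replicate 5 (next 861.3) and 3397 in DSW 2013 replicate 1 (next 1236). For GT_EA516_an_s_xh_2370, DSW 2011 replicate 5 stood at 0.797 (next −3.67) and US2 2013 replicate 6 at −0.445 (next −2.23). For GT_EA516_an_as_sp_2221, DSK1 2012 replicate 3 stood at −5.77 (next −4.15), and for GT_EA516_an_s_sp_2358, US2 2011 replicate 6 stood at −0.952 (next −5.39).

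The difference from US2 itself differed between years in 7 tests. At DSW it did so in 30 probes for 2014 against 2011, 15 for 2012 against 2011, 1269 for 2013 against 2011, 29 for 2013 against 2012 (1 with the slide as a fixed block in the same model) and 489 for 2014 against 2013. At DSK1 it did so in 6 probes for 2014 against 2011 and 2 for 2014 against 2013.

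With 1 array left out, 6 of these counts moved by over 1.5 times; those for 2014 against 2011 at both sites and for 2014 against 2013 at DSW are given in the report. For DSW in 2012 against 2011 the count was 27 without US2 2011 replicate 4, 26, 6, 24 and 60 without DSW 2011 replicates 1, 2, 4 and 5, and 23 without US2 2012 replicate 6. For DSW in 2013 against 2012 it was 17, 12, 13, 13 and 15 without US2 2012 replicates 1 to 5, and 14, 15, 45, 11, 15 and 46 without DSW 2012 replicates 1 to 6. It was 18, 14 and 6 without US2 2013 replicates 2 to 4, and 15, 14, 147, 8, 4, 10 and 131 without DSW 2013 replicates 1 to 7. For DSK1 in 2014 against 2013 it was 1, 11 and 1 without DSK1 2013 replicates 1, 3 and 4, 1 and 8 without US2 2014 replicates 3 and 4, and 21, 1 and 1 without DSK1 2014 replicates 4, 6 and 7. The DSK1 counts of 0 became 1 and 2 for 2013 against 2011 without US2 2011 replicate 6 and US2 2013 replicate 7. For 2013 against 2012 the DSK1 count became 4 without US2 2012 replicate 6, US2 2013 replicate 7 or DSK1 2013 replicate 3.

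Each count was set against 100 splits of the same arrays, the real grouping among them. In 2013 the arrays of one specimen number were permuted as separate fish. For DSW against US2, 1 of the 100 splits gave as many probes in 2011 (real 297, highest other 25), 100 in 2012, by necessity (real 0 by limma, where 593 had an unadjusted p under 0.05 and ANOVA called 1 with and 368 without adjustment; highest other 4), 2 in 2013 (real 917, highest other 954) and 5 in 2014 (real 1, highest other 22). For DSK1 against US2, 3 of the 100 did so in 2011 (2, highest other 26), 1 in 2012 (6, highest other 2), 8 in 2013 (1, highest other 48) and 3 in 2014 (6, highest other 47). For DSK1 against DSW, 2 did so in 2011 (2, highest other 3), 1 in 2012 (80, highest other 10), 2 in 2013 (1136, highest other 1636) and 100 in 2014, by necessity (0 by limma, 446 unadjusted, ANOVA 2 with and 251 without adjustment; highest other 310). The split with 954 kept 10 of the 14 arrays in place, and that with 1636 kept 1 of 13, which is nearly the mirror of the real grouping. Other splits gave several times the real count, as at DSK1 in 2011, 2013 and 2014; these may point to a structure of the samples, which was not tested.

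For US2 between years, 11 of the 100 splits gave as many probes in 2012 against 2011 (real 1, highest other 163), 1 in 2013 (328, highest other 37) and 5 in 2014 (9, highest other 28). For DSW, 1 did so in 2014 against 2011 (30, highest other 8), 1 in 2012 against 2011 (15, highest other 12), 1 in 2013 against 2011 (1269, highest other 472), 3 in 2013 against 2012 (29, highest other 262) and 1 in 2014 against 2013 (489, highest other 20). For DSK1, 3 did so in 2014 against 2011 (6, highest other 110) and 5 in 2014 against 2013 (2, highest other 17). In 2012 against 2011, 2013 against 2011 and 2013 against 2012 the real DSK1 count was 0 by limma (606, 470 and 771 unadjusted; no ANOVA was run), and 100, 100 and 100 of the splits gave as many, by necessity (highest other 49, 1 and 74). The splits with 163, 262 and 110 probes, several times the real count, may point to a structure of the samples, and none was tested. For the counts above 0, chance was not excluded at 5 or more of the 100 splits, and for a real count of 0 the splits say nothing. Fewer than 5 does not exclude chance either, as the splits were few and no correction over the comparisons was made.

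The difference of DSW from US2 in 2013 was weighed against batch, probe composition and a single array. In models of all 12 groups 1245 probes passed with no block, 1245 with the slide as a fixed block and 1303 with the slide row as a block. Within the year, beside the 917, 991 passed with the GC trend removed and 700 without the brightest array, so none of these accounts for the count alone. The called probes shifted less at US2 than at DSW, with a ratio of the median absolute shifts from the other years of 0.361, which argues against a change of the upstream fish as the main source over the whole list but not against a part of it. From 2011 to 2013 US2 moved in the direction of the DSW difference in only 105 of the 564 higher and 79 of the 353 lower probes. Most moved the other way, in part by construction, since the list was chosen on the same US2 fish of 2013. An axis that also moves between years at US2 was left open, since over the called probes r was −0.495 with the change from US2 2011 to US2 2014 (highest permuted value 0.597, permutation p = 0.17). An effect of the DSW site in 2013 is therefore a candidate explanation, but the site and anything else in which its fish differ cannot be told apart.

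The difference of DSW from US2 in 2011 was weighed in the same way. In models of all 12 groups 348 probes passed with no block, 341 with slide blocks and 391 with the slide row as a block, and within the year 277 passed with the GC trend removed, beside 297. The called probes shifted from the other years by a median of 0.293 at US2 and 0.632 at DSW (log2), a ratio of 0.464. The other DSW years include 2013, when median log2 differences from US2 were −0.512 for the higher and 0.105 for the lower probes. These opposite differences can widen the DSW shift, so the ratio does not decide whether US2 was the main source. DSK1 of 2011 lay on the DSW side of the same US2 fish in 134 of 136 higher and 155 of 161 lower probes. That can also arise by construction, as the list was chosen on those US2 fish. From 2011 to 2014 US2 moved toward the DSW levels of 2011 in 132 of the 136 higher and 159 of the 161 lower probes, which holds in part by construction since the list was chosen on the same US2 fish of 2011. For GT_EA516_an_s_xh_2370 the mean was 3.25 at US2 in 2011 against −1.03, −2.69 and −0.23 in the later years, and −3.83 at DSW in 2011 against 0.21, −4.31 and 1.99. Over the called probes r with the change from US2 2013 to US2 2014 was 0.151 (highest permuted value 0.663, permutation p = 0.76). A change at the DSW site in 2011 may be part of the source, as a hypothesis, and how much of the difference lies with the US2 fish of 2011 was left open.

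The rise of the custom probes CUST_3_PI428058183 and CUST_4_PI428058183 at DSW in 2013 was weighed against a few fish, the slide and the spot. For each probe 6 of the 7 DSW arrays lay above every US2 fish of that year. The smaller mean rise of the pair within a slide row was 6.9 on the log2 scale, beside 7.57 over all arrays. The larger of the median differences between the 2 spots of a probe was 0.156 on the log2 scale. High values also occurred in fish of other groups, upstream ones included. For CUST_4_PI428058183 the highest was 2.985 at US2 and 7.714 at DSW in 2012, and for CUST_3_PI428058183 it was 3.438 and 8.078, beside means of 2.79 and 3.07 at DSW in 2013. A change in the livers of most DSW fish of 2013 may be the source, but high levels are not particular to that site or year, and what the probes measure was not determined.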

How the results depend on the processing

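The day of scanning, the slide row, the GC trend and the removal of arrays with under 50% of spots well above background were chosen after the data were seen. Counts below are probes past the threshold by limma unless ANOVA is named, written for DSW vs US2 (D), DSK1 vs US2 (K), DSK1 vs DSW (KD) and US2 between years (U), with the years following. Of the 56 pairs of a named probe and a comparison refitted, 10 of them picked after their values were seen, 1 changed direction: GT_EA516_un_s_sp_43129 for D 2014, which had not passed, from −0.26 to 0.02107 without US2 replicate 5 (range −0.4816 to 0.02107 with each array left out). With no filter on dim probes all 17 counts fixed beforehand lay within 1.5 times the reported ones. The cause of the changes was not tested, except that fewer probes or fewer arrays entered some alternatives.

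With normexp and quantile normalisation, K 2012 gave 2 and U 2012 against 2011 gave 7. Quantile normalisation alone gave 1 for D 2012, 2 for K 2012, 15 for KD 2011, 4 for U 2012 against 2011 and 15 for U 2014 against 2011. The authors' value table gave 1 for D 2012, 2 for K 2012, 4 for KD 2011 and 4 for U 2012 against 2011. Among probes well above background on every array, which are fewer, D 2013 gave 521, K 2011 0, K 2012 3, KD 2011 0, KD 2013 697, K 2014 against 2011 2, U 2012 against 2011 0 and U 2013 against 2011 176.

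Fitted with the slide as a fixed block, D 2012 gave 4, D 2014 0, K 2011 0, K 2012 0, K 2013 0, K 2014 0, KD 2011 13, KD 2012 140, K 2014 against 2011 1, U 2012 against 2011 0 and U 2014 against 2011 2. As a random block it gave 3 for D 2012, 0 for D 2014, 0 for K 2011, 0 for K 2013, 1 for K 2014, 22 for KD 2011, 229 for KD 2012 and 3 for U 2014 against 2011. With all 12 groups in 1 model, D 2012 gave 1, D 2014 0, K 2011 0, K 2013 0, K 2014 3, KD 2011 22 and KD 2012 224. The day of scanning as a block gave 2 for D 2012, 0 for D 2014, 0 for K 2011, 10 for K 2012, 0 for K 2013, 26 for KD 2011 and 256 for KD 2012. The slide row as a block gave 1 for D 2012, 0 for D 2014, 0 for K 2011, 10 for K 2012, 0 for K 2013, 3 for K 2014, 22 for KD 2011 and 299 for KD 2012. For counts within a year these fits also pool the spread over all years, as the model of all groups does with no block. Against that model the slide as a fixed block moved D 2012 from 1 to 4, K 2012 from 8 to 0, K 2014 from 3 to 0, KD 2011 from 22 to 13 and KD 2012 from 224 to 140. The counts between years come from that model already, so pooling does not account for their moves under the slide block; whether slide effects or the loss of precision do was not tested.

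With repeated specimen numbers averaged, K 2013 gave 0 and KD 2013 gave 634, from 1 array fewer in each group with such a number. With the GC trend removed, D 2014 gave 0, K 2013 0, K 2014 3, KD 2011 10, KD 2012 122, K 2014 against 2011 1 and U 2012 against 2011 8. Without the 4 dim arrays, D 2014 gave 0, KD 2011 0, KD 2012 17, D 2014 against 2011 18, K 2014 against 2011 0, U 2012 against 2011 7 and U 2014 against 2011 0.

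One-way ANOVA with adjustment of the test over all sites, but not of the pairwise contrast, gave 72 for D 2011, 1 for D 2012, 2 for D 2014, 42 for K 2011, 3 for K 2012, 151 for K 2013, 61 for KD 2011, 4 for KD 2012 and 2 for KD 2014. Without adjustment it gave 1011, 368, 1773 and 244 for D in 2011 to 2014, K gave 392, 422, 459 and 344, and KD gave 685, 705, 1755 and 251. Under limma the unadjusted counts for D were 1460, 593, 2233 and 440.

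Of the differences between years added after the data were seen, D 2013 against 2012 (29) gave 16 with normexp and quantile normalisation, 17 with quantile normalisation, 17 with no filter, 1 with the slide as a fixed block, 10 with repeated specimen numbers averaged and 13 without the dim arrays. D 2012 against 2011 (15) gave 28 with the slide as a fixed block and 33 among probes well above background on every array. K 2014 against 2013 (2) gave 0 with the slide as a fixed block, 9 among probes well above background on every array, and 1 with quantile normalisation, the authors' value table, repeated numbers averaged or the dim arrays removed. K 2013 against 2012 (0) gave 1 with normexp and quantile normalisation. Under normexp and quantile normalisation the fold of 35 of the 56 pairs was smaller by over 1.5 times.

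With each array left out in turn, the counts ranged from 181 to 449 for D 2011, 0 to 12 for D 2012, 543 to 1444 for D 2013 and 0 to 2 for D 2014. They ranged from 1 to 9, 0 to 9, 0 to 8 and 3 to 21 for K in 2011 to 2014, and from 0 to 36, 0 to 233, 735 to 1588 and 0 to 0 for KD. For 2014 against 2011 they were 20 to 50 for D and 0 to 11 for K, and for U they were 0 to 6 in 2012, 158 to 385 in 2013 and 0 to 13 in 2014. The report names each array that moved a count by over 1.5 times.

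The counts of D 2011 and D 2013 were above 180 and 520 under each alternative fitted by limma, and the counts of K stayed at 21 or below. No paired analysis was possible because the replicate numbers follow the order of the samples in the series and pair no fish between sites. Arrays of the lower slide row had less signal over background, which limits what can be read of dim probes there.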

Other observations

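The tests in this part were written after the values had been seen. The 5 probes with the largest rises at DSW in 2013 include the custom pair and 3 further probes, picked for that rise, and the hypothesis was that their levels vary together from fish to fish outside that group. GT_EA516_an_as_sp_875 did so with the mean of the custom pair (r = 0.888, rho = 0.820, permutation p = 1e-05, the smallest the permutations can give, adjusted 3e-05 over 3 tests, 72 arrays). Without the 2 farthest fish r was 0.877, and within the 3 days of scanning it was 0.922, 0.863 and 0.903. GT_EA516_un_s_sp_43129 had r = 0.438 (rho = 0.478, permutation p = 0.00022, adjusted 0.00033, 71 arrays), 0.566 without the 2 farthest fish, and 0.176, 0.615 and 0.519 within days. GT_EA516_un_s_sp_41772 had r = −0.0099 (rho = 0.0435, permutation p = 0.94, adjusted 0.94, 72 arrays), 0.0892 without the 2 farthest fish, and −0.151, 0.269 and −0.319 within days. The first and second of these probes may thus vary with the custom pair, the second less closely and with 27 of the 72 arrays well above background. The last was well above background on 8 of the 72 arrays, so its correlation says nothing for or against the hypothesis. These probes share 8 bases or fewer in a row with the pair.

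The first principal component of all arrays held 14.1% of the variance, with group accounting for 0.525 of it, slide for 0.268 and the day of scanning for 0.0708. Each factor was fitted alone, so the shares can overlap, and factors with more levels account for more by chance. The second held 6.98%, with group accounting for 0.509 of it and slide for 0.088. The third held 6.70%, of which the share of spots well above background accounted for 0.250 and the slide row for 0.101. In models with the group, 522 probes passed for the slide, 709 for the day of scanning and 698 for the slide row.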
